A study of Mus musculus with 24 samples.

How the data were processed

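Liver RNA of male C57BL/6 mice aged 7 to 8 weeks was measured on 24 single-colour Agilent arrays with 55681 probes. Groups, doses and diets were taken from the sample labels. The vehicle is not given, the label protocol distinguishes no strands, and the genome build of the probe coordinates is not given in the sources used here. The coordinates were not used, since 9.15% of the 31166 probes with coordinates fell inside their gene in GRCm38.

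Per the labels, the authors extracted signals with Agilent Feature Extraction 10.7.3.1. The deposited workbook gives an unscaled intensity for every probe and array, and these values were used here. The authors also deposited log2 values, which were recomputed from the intensities as log2 signal minus the array's 75th percentile, minus the probe's median over a set of 8 arrays. The largest difference between recomputed and deposited values was 0.00552. The centring shows 3 such array sets; probe baselines differ by 8.17e-08 within a set and by at least 0.149 between sets. Whether a set is a slide is not stated. The deposited series table holds the same log2 values within 5e-07. The deposited workbook also holds p-value columns, which the authors made with one-way ANOVA over 3 or 5 groups, before and after correction. These were not used for any result.

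The 75th percentile of intensity ran from 158 to 399.6 between arrays, and between 33.7% and 48.6% of probes lay under 2 times the array's 5th percentile. Correlations between arrays ran from 0.946 to 0.985. No detection flags or negative control values came with the files, so no filter on dim probes was applied. Probe symbols were updated from a reference table by Entrez number (31235 probes matched, 2045 symbols changed). Of 33201 probes with a symbol, the one with the highest mean over the 24 arrays stands for its gene, which gives 24136 genes; 22480 probes have no symbol.

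After the data were seen, low fat arrays 1 and 3 were found to be unusually alike. If 2 arrays hold different RNA, the 2 probes of a gene report the same difference. Over 1473 genes with 2 probes, the differences between arrays 1 and 3 correlated at 0.0137 (permutation p = 0.579, 1e+05 permutations), against 0.194 to 0.799 for the other array pairs. Still, 23 probes differed by more than 2-fold (at least 84 in any other pair), 1 of Xist among them (1.60 and 8.75), so whether the RNA is the same stays open. The 2 arrays were averaged and counted as 1 sample, a departure from the planned 24 samples, which leaves 23 samples. The alternative with 24 samples was also run.

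Values were log2 intensity minus the array's 75th percentile. Groups were compared in 1 limma fit (limma 3.58.1, R 4.3.3; lmFit, contrasts, eBayes) with a mean per group and no covariates, two-sided, with Benjamini-Hochberg adjustment over 24136 genes and a threshold of 0.05. The 14 comparisons were high fat and MCD against low fat, MCD against high fat, each of the 4 treatments against high fat and against low fat, and the extract doses and EGCG against each other. A gene under 2 times the array's 5th percentile in every sample of one group has its fold given as a bound against that floor. Where only some samples of a group were under it, the change is given as measured, and background makes it too small in size.

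Gene lists written before the data were examined (20 for processes, 14 for cell types or tissues) were tested with camera at a preset correlation of 0.01 between genes and adjusted over the 34 lists. An estimated correlation and a fit with the array set as a block were alternatives.

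The return towards low fat was the correlation across genes of the diet change with the treatment change, with the high fat samples split 2 and 2 over all 6 splits. The overlap of treatments used shared genes and correlations with the same splits. Both were set against 100 simulations of unchanged groups. The fit was tested on simulated data, with independent noise per gene and sample and 50 genes changed at each of 4 sizes. For high fat against low fat, 22%, 50%, 76% and 84% of genes changed 1.5, 2, 4 and 8-fold passed, with 12 of 128 calls false. For MCD against low fat the shares were 6%, 36%, 76% and 88% (2 of 105 false), for green tea 2% against high fat 10%, 34%, 72% and 94% (6 of 111 false), and for EGCG against green tea 2% 12%, 26%, 66% and 84% (12 of 106 false).

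Alternatives were quantile normalization, median centring, no filter on dim probes, only the brighter probes (above the median level), the mean over a gene's probes, every probe on its own, a fit of the 2 groups alone, array weights, a trend and robust prior, the deposited log2 values, the array set as a block, a replicate block, an added 2-fold threshold and leaving out each sample, for gene counts, for lists and for the mean of each list that passed (the last chosen after the data were seen). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.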

Results

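The series measured gene expression in the livers of male C57BL/6 mice with single-colour Agilent arrays of 55681 probes. The 24 arrays fall into 7 groups. Low fat mice ate standard pellets (4 arrays), and high fat mice ate a diet with 60% of its energy from fat and 1% cholesterol and drank 30% fructose (4 arrays). Per the treatment descriptions in the labels, mice on the high fat diet received green tea extract at 100 mg/kg (labelled 1%, 3 arrays) or 200 mg/kg (labelled 2%, 4 arrays), the green tea catechin epigallocatechin gallate (EGCG) at 20 mg/kg (3 arrays), or the statin atorvastatin at 20 mg/kg (3 arrays). MCD mice ate a methionine-choline deficient diet, a model of steatohepatitis (3 arrays). Other label fields disagree: one places MCD and treated samples in the high fat group, and the housing notes give all mice a standard diet. The comparisons below rest on the treatment descriptions. Low fat arrays 1 and 3 differed without the agreement between probes of a gene that all other array pairs showed, and were counted as 1 sample, low fat 1, which leaves 23 samples and 3 low fat samples. The 75th percentile of raw signal ran from 158 to 223.9 in low fat, 176 to 253 in high fat, 218 to 324 in treated and 237 to 399.6 in MCD arrays. The arrays form 3 sets of 8 that the authors centred separately, and each set holds at least 1 sample of every group. Values are log2 changes ± standard error with limma's adjusted p over 24136 genes. A gene passed at an adjusted p under 0.05, and each gene given as a largest change separated every sample of one group from every sample of the other. The median gene lay at -0.01 for high fat against low fat, between -0.10 and -0.14 for the treatments against high fat, and at -0.23 for MCD against low fat. After quantile normalization it lay between -0.02 and 0.00 in these comparisons. Changes are given without subtracting that shift, and the list tests compare each list with all other genes.

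**Figure D1:**
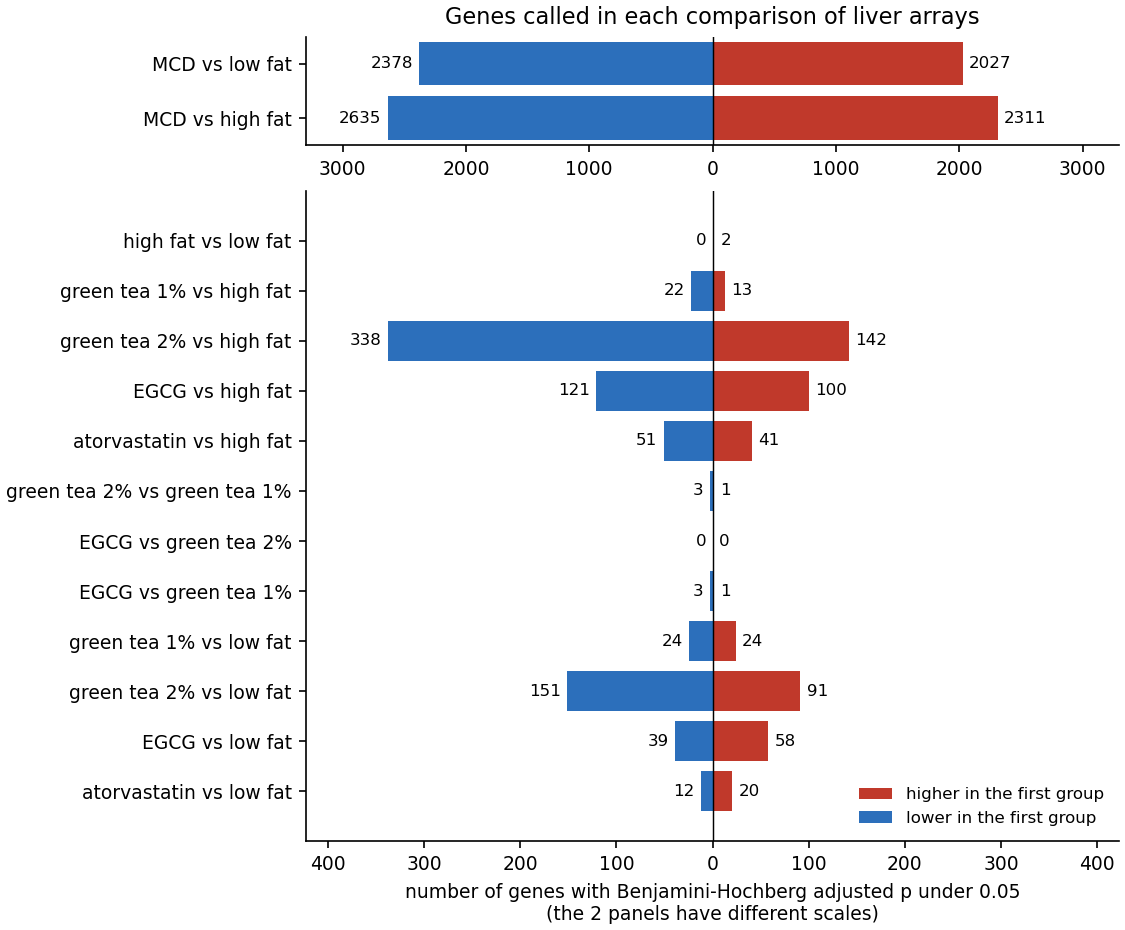
Number of genes with an adjusted p under 0.05 in each comparison (bars; higher to the right, lower to the left; limma, 24136 genes), with the MCD comparisons on their own scale. MCD against low fat reached 2027 higher and 2378 lower genes, green tea 2% against high fat 142 and 338, and high fat against low fat 2 and 0.

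High fat against low fat compares the high fat diet with standard pellets of unstated composition. With 4 high fat and 3 low fat samples, 2 genes passed and both were higher. Sptlc3 (Entrez gene 228677), a subunit of the enzyme that starts sphingolipid synthesis, was higher by 2.24 ± 0.32 (adjusted p = 0.0347). Its low fat signal was near background, so its fold is at least 2.50-fold higher. Slc10a2 (Entrez gene 20494), a sodium-dependent bile acid transporter, was higher by 1.43 ± 0.22 (adjusted p = 0.0419). In array sets 1, 2 and 3, Slc10a2 was higher by 1.27, 1.33 and 1.75. None of the 23 genes fixed beforehand passed: they ran from -1.09 for the desaturase Scd1 to 1.86 ± 0.57 for Cyp7a1, the rate-limiting enzyme of bile acid synthesis (adjusted p = 0.774). The lipid uptake gene Cd36 was at -0.26 ± 0.32 and the fatty acid synthase Fasn at 0.46 ± 0.47.

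Of the 34 gene lists, 7 shifted in high fat livers with the preset correlation and none with an estimated one, and no member of the 7 passed over all genes. Endoplasmic reticulum stress genes lay higher by 0.49 on average (15 of 21 above 0; adjusted p = 7.07e-07, and adjusted p = 0.662 with an estimated correlation), with Creld2 at 1.78 ± 0.46. Their mean was 1.10, 0.42 and -0.13 in array sets 1, 2 and 3. Circadian clock genes lay higher by 0.45 (adjusted p = 7.07e-07, and adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone, 9 of its 21 members were higher and 2 lower. Per2 was at 1.49 ± 0.31 and Dbp at 1.16 ± 0.26, and the clock mean was 0.49, 0.45 and 0.30 in the 3 sets. Matrix genes lay higher by 0.29 (adjusted p = 0.763; 0.05, 0.58 and -0.11 in the sets), cell cycle genes by 0.27 (adjusted p = 0.745) and female-biased liver genes by 0.48 (adjusted p = 0.745), each p with an estimated correlation. Respiratory chain genes lay lower by -0.13 and proteasome and ribosome genes by -0.14 (adjusted p = 0.904 with an estimated correlation for both). After quantile normalization the respiratory chain and proteasome and ribosome means were both -0.06, and the female-biased list (adjusted p = 0.0788) and the respiratory chain list (adjusted p = 0.0549) no longer passed. The set means were 0.12, 0.80 and 0.25 for female-biased and 0.18, 0.39 and 0.13 for cell cycle genes. Without high fat 3 the matrix mean was 0.19. Without high fat 4 the cell cycle mean was 0.17, female-biased 0.29 and matrix 0.16, and the cell cycle, female-biased and matrix lists no longer passed. Without high fat 6 the matrix mean was 0.44 and respiratory chain -0.07, and the female-biased list no longer passed. Without low fat 1 the ER stress mean was 0.18. Without low fat 4 the respiratory chain mean was -0.06 and proteasome and ribosome -0.05, and the cell cycle, female-biased and proteasome and ribosome lists no longer passed.

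At an unadjusted p under 0.05, limma listed 930 genes, fewer than by chance, and the median 95% interval reached 0.65 to either side. Calls were lost, with the largest adjusted p in brackets, by Slc10a2 without low fat 1, 4 or 6 or high fat 3, 4 or 6 (0.222) and Sptlc3 without low fat 1 or 6 or high fat 3 or 4 (0.187). Without low fat 6, high fat 3 or high fat 4 the count was 0, and without high fat 1 it was 5. The genes and their direction moved too. Without low fat 1, 3 genes passed, 0 higher and 3 lower, and 0 of them were among the 2. Without low fat 4, 3 genes passed (1 higher and 2 lower), and 1 of them was among the 2. Without high fat 6, 2 genes passed and 1 of them was among the 2. The number of shifted lists was 4 without high fat 4, and 11 without high fat 1, low fat 6 or low fat 1.

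MCD against low fat asks what a diet that produces steatohepatitis does to the liver. The MCD livers lost the male pattern of gene expression: all 19 male-biased liver genes fell, by -4.24 on average (adjusted p = 6.97e-25), and 8 of 17 female-biased genes rose. Of the 15 lists that shifted, only the male-biased one also passed with an estimated correlation. In all, 2027 genes were higher and 2378 lower in the 3 MCD than in the 3 low fat samples. With the array set as a block the counts were 2961 and 4216, and all 4405 genes stayed among them.

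The largest rises were the sulfotransferases Sult2a2 (at least 1229-fold higher), Sult2a6 (10.38 ± 0.62, adjusted p = 3.83e-09) and Sult1e1 (9.50 ± 0.76), the cytochrome P450 Cyp3a44 (10.50 ± 0.73, adjusted p = 2.22e-08) and the matrix protease Mmp7 (at least 321-fold higher). The largest falls were the organic anion transporter Slco1a1 (-9.47 ± 0.44, adjusted p = 2.62e-10), the steroid dehydrogenase Hsd3b5 (-9.40 ± 0.73), the fatty acid elongase Elovl3 (-8.34 ± 0.41) and the pseudogene Serpina4-ps1 (at least 160-fold lower). Male-biased genes kept their call with an estimated correlation (adjusted p = 0.0106), with set means of -4.13, -4.65 and -3.95. The female-biased list averaged 2.42 higher (adjusted p = 5.08e-07, and adjusted p = 0.102 with an estimated correlation), led by Cyp3a44 and Sult2a1 (8.57 ± 0.65).

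Cholesterol synthesis and SREBP2 target genes averaged 1.33 higher (adjusted p = 2.26e-10, and adjusted p = 0.226 with an estimated correlation; 1.86, 0.83 and 1.30 in the sets). Of 25 members, 16 rose and 3 fell (17 and 3 adjusted over the list alone). Squalene epoxidase Sqle rose 47.2-fold (5.56 ± 0.66), while Acat2 fell by 2.05 (SE 0.24). Scd1 fell 219-fold (-7.77 ± 0.67), the lipid droplet protein Cidec rose by 3.90 ± 0.80 (adjusted p = 0.00177), and Fasn was at 0.97 ± 0.50 (adjusted p = 0.217). The adjusted p beside each list mean is with an estimated correlation. Fatty acid oxidation genes averaged -0.45 (11 of 28 fell and 2 rose, 12 and 2 adjusted over the list alone; adjusted p = 0.697; set means -1.06, -0.41 and 0.12). Without low fat 1 that mean was -0.19 and the list no longer passed, and without low fat 6 the mean was -0.70. The pyruvate dehydrogenase kinase Pdk4 rose by 3.71 ± 0.65. Bile acid and sterol export genes averaged -0.70 (8 of 19 fell, 10 adjusted over the list alone with 1 that rose; adjusted p = 0.467), with the oxysterol hydroxylase Cyp7b1 at -3.33 ± 0.45.

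Each list's adjusted p is with an estimated correlation. Macrophage and Kupffer cell markers averaged 1.56 higher (11 of 21 rose, 12 adjusted over the list alone with 1 that fell; adjusted p = 0.117). Gpnmb rose by 8.53 ± 0.72, from a low fat signal near background in 2 of 3 samples, the lipid-associated macrophage receptor Trem2 by 3.80 ± 0.49 and Cd68 by 1.44 ± 0.25. Neutrophil markers averaged 1.96 higher (5 of 13 rose and 1 fell; adjusted p = 0.467), with S100a8 at 4.26 ± 0.76. Cholangiocyte markers averaged 1.21 higher (6 of 11 rose and 1 fell; adjusted p = 0.087), with Epcam at 2.58 ± 0.35. Matrix genes averaged 1.16 higher (12 of 24 rose, 15 adjusted over the list alone; adjusted p = 0.152; 1.59, 1.03 and 0.85 in the sets), with osteopontin, Spp1, at 2.88 ± 0.26 and Timp1 at 2.13 ± 0.40, while Col1a1 was at 1.04 ± 0.43 (adjusted p = 0.11). Stellate cell markers averaged 0.42 higher (3 of 16 rose and 1 fell; adjusted p = 0.538) and cell cycle genes 1.07 higher (6 of 23 rose; adjusted p = 0.117), with Ccnd1 at 2.46 ± 0.40. Red blood cell markers averaged 1.36 higher (3 of 10 rose and 1 fell; adjusted p = 0.659). The set means were 1.43, 3.81 and 0.63 for neutrophil and 0.11, 2.96 and 1.00 for red blood cell markers. Without MCD 4 the neutrophil mean was 1.06 and red blood cell 0.40, and the red blood cell list no longer passed.

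Each list's adjusted p is with an estimated correlation. Interferon response genes averaged -1.04 (14 of 24 fell, 17 adjusted over the list alone; adjusted p = 0.276; set means -0.70, -1.21 and -1.22), with Ifit3 at -2.22 ± 0.31. Respiratory chain genes averaged -0.50 (16 of 31 fell, 24 adjusted over the list alone; adjusted p = 0.467). Hepatocyte markers averaged -0.51 (12 of 22 fell, 14 adjusted over the list alone; adjusted p = 0.538), with albumin, Alb, at -0.64 ± 0.15 (adjusted p = 0.0067). After quantile normalization the fatty acid oxidation mean was -0.26, respiratory chain -0.27 and hepatocyte -0.08, and the hepatocyte list no longer passed (adjusted p = 0.224). Of the other genes fixed beforehand, the chemokine Ccl2 was at 1.55 ± 0.56 (adjusted p = 0.0654), the NRF2 target Nqo1 at 1.01 ± 0.35 (adjusted p = 0.0518), Cyp7a1 at 0.48 ± 0.61 (adjusted p = 0.634) and Saa1 at -1.10 ± 0.85 (adjusted p = 0.439).

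MCD against high fat sets the 2 disease models side by side. The 3 MCD livers had 2311 genes higher and 2635 lower than the 4 high fat livers (3455 and 4208 with the array set as a block, which kept 4945 of the 4946). The largest rises were Cyp3a44 (11.10 ± 0.69, adjusted p = 2.89e-09), Sult2a2 (at least 1223-fold higher) and Sult2a6 (10.75 ± 0.58). The largest falls were Serpina4-ps1 (at least 549-fold lower), Cfd, the serine protease adipsin (-9.28 ± 0.92, adjusted p = 9.84e-07), and Slco1a1 (-8.90 ± 0.42). Cfd changed by -9.09, -11.13 and -6.39 in array sets 1, 2 and 3. All 19 male-biased genes fell, by -4.07 on average, and that list passed with an estimated correlation (adjusted p = 0.0118). Macrophage markers averaged 1.54 higher (11 of 21 rose; adjusted p = 0.206 with an estimated correlation). Matrix genes averaged 0.87 higher (10 of 24 rose, 12 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). Cholesterol synthesis genes averaged 1.20 higher (15 of 25 rose and 3 fell, 19 and 3 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). Interferon response genes averaged -1.01 (15 of 24 fell; adjusted p = 0.339 with an estimated correlation). Other lists passed with the preset correlation and lost their calls with an estimated one, whose adjusted p is in brackets. They were neutrophil markers at 1.72 (5 of 13 rose and 1 fell; adjusted p = 0.554), cholangiocyte markers at 1.09 (7 of 11 rose and 1 fell; adjusted p = 0.144), red blood cell markers at 1.63 (5 of 10 rose and 1 fell), stellate cell markers at 0.37, hepatocyte markers at -0.40 (12 of 22 fell and 1 rose) and respiratory chain genes at -0.37 (each adjusted p = 0.633). With an estimated correlation female-biased genes at 1.94 (adjusted p = 0.284), cell cycle genes at 0.80 (adjusted p = 0.301), proteasome and ribosome genes at 0.24 (adjusted p = 0.677), bile acid and sterol export genes at -0.68 (adjusted p = 0.493) and fatty acid oxidation genes at -0.39 (adjusted p = 0.708) lost theirs too. Without MCD 4 the neutrophil mean was 0.83 (adjusted p = 0.055) and red blood cell 0.67 (adjusted p = 0.0725), so both lists no longer passed, hepatocyte was -0.60 and cell cycle 0.52. Without MCD 8 the cell cycle mean was 1.27. The stellate cell list no longer passed without high fat 1 (0.26, adjusted p = 0.0729) or after quantile normalization (adjusted p = 0.0501). There the hepatocyte mean was -0.05 and no longer passed (adjusted p = 0.327), respiratory chain was -0.21, fatty acid oxidation -0.26 and proteasome and ribosome 0.42.

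**Figure D2:**
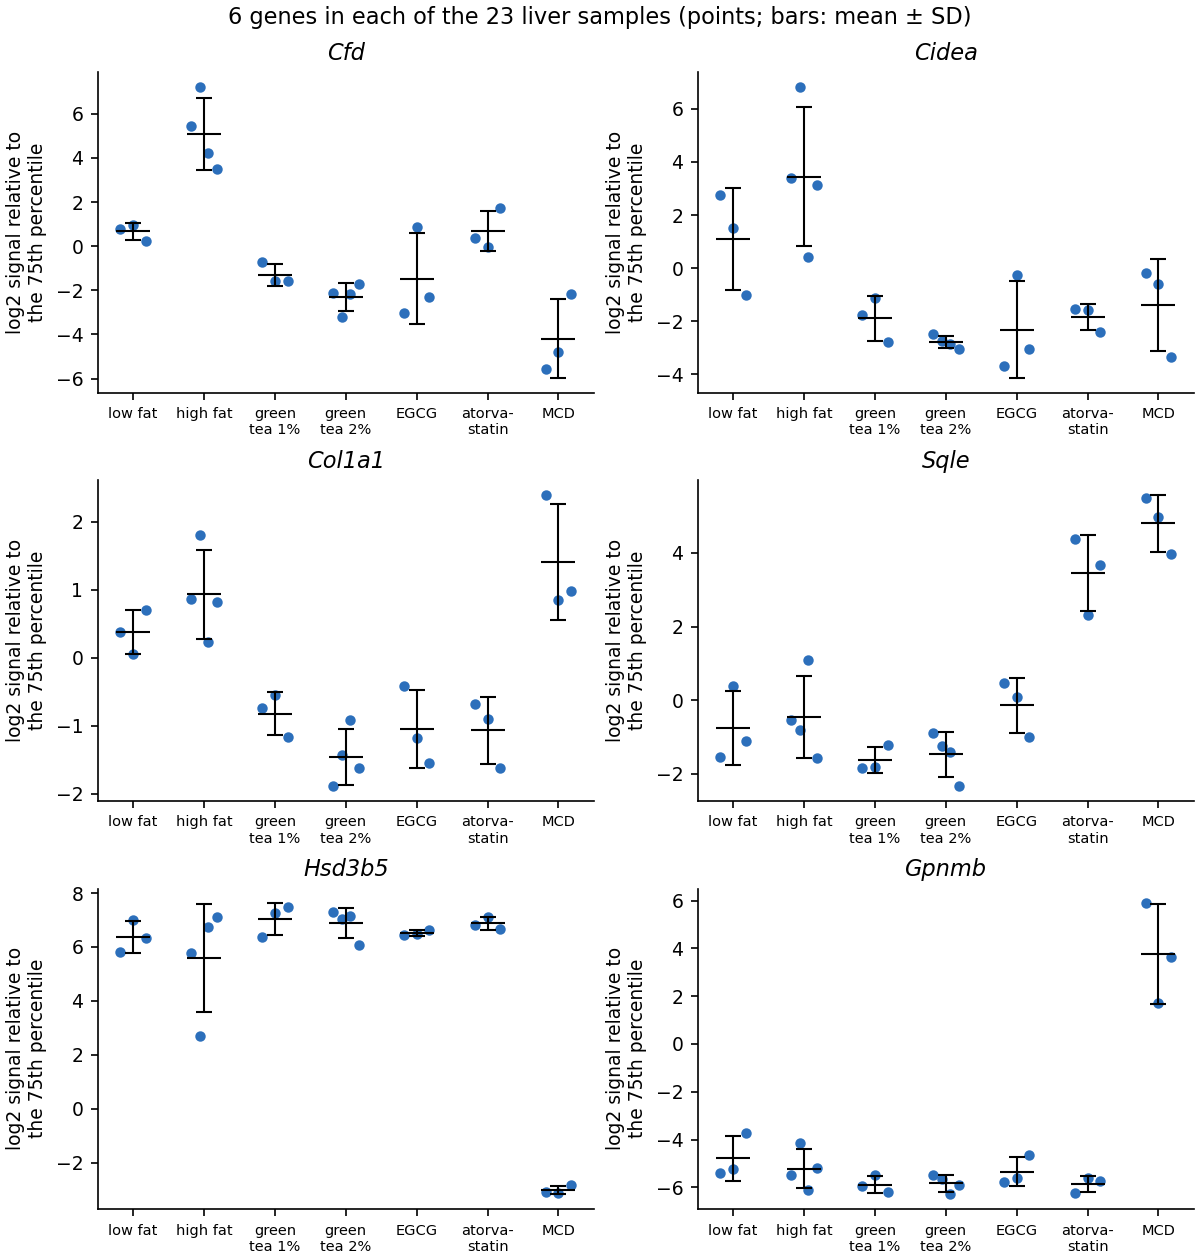
Level of 6 genes (log2 signal relative to the array's 75th percentile) in each of the 23 liver samples (points), with the mean and SD of each group (bars). Cfd averages 5.09 in high fat livers and lies below 2 in all other samples; Hsd3b5 falls and Gpnmb rises in the 3 MCD livers, and Sqle is highest in the atorvastatin and MCD livers.

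The 4 treatments against high fat ask whether green tea extract, its catechin EGCG, or a statin changed the liver on that diet. In each treatment, genes of lipid storage, extracellular matrix, endoplasmic reticulum stress and the cell cycle lay lower on average than in high fat livers, and clock genes lay higher. None of these lists passed with an estimated correlation in any of the 4 treatments. The adipose tissue list averaged lower too, at -0.85, -1.04, -1.01 and -0.86 for green tea 1%, green tea 2%, EGCG and atorvastatin, and did not pass (adjusted p = 0.131, 0.169, 0.103 and 0.0884). With atorvastatin 9 of 25 cholesterol synthesis genes rose, and that list too lost its call (adjusted p = 0.0808 with an estimated correlation). A set of 14 genes passed in all 4 treatments, 5 higher and 9 lower. The lower ones included Cfd, the chaperone regulator Creld2, the ER-associated degradation genes Sel1l and Syvn1, the collagen chaperone Serpinh1, and Sptlc3 and Slc10a2. The higher ones were Fhad1, Fzd6, Kdf1, Odf2 and Ttc6, with Fzd6 higher by 1.30 to 1.62. These genes were named because they passed in all 4, after their values were seen, and all 4 comparisons share the same 4 high fat samples.

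**Figure D3:**
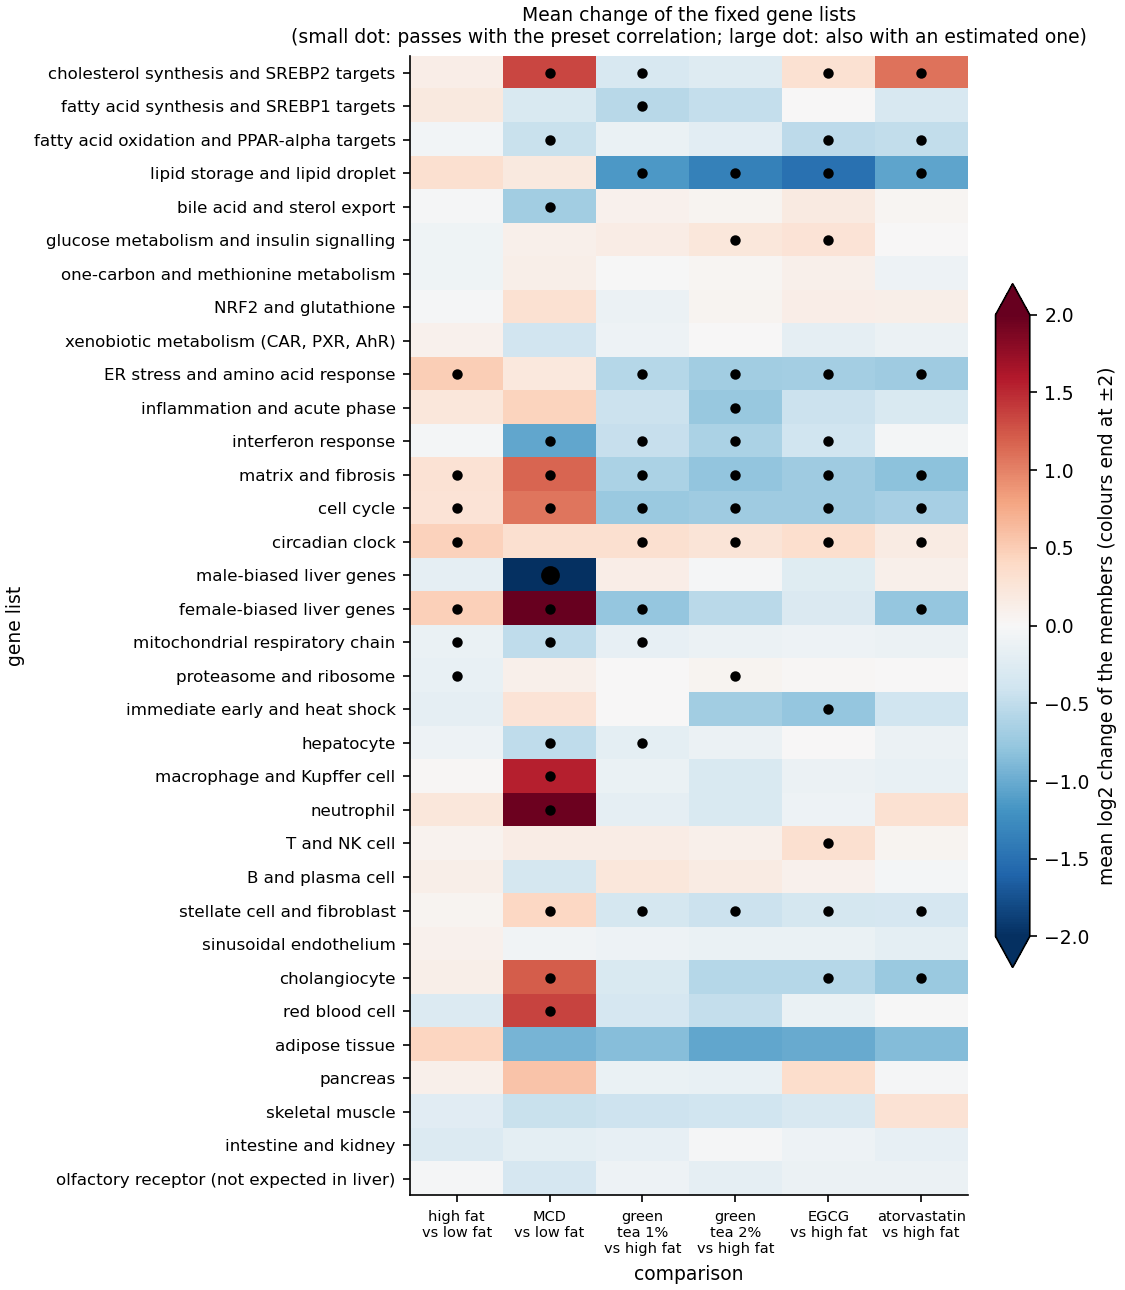
Mean log2 change of the members of each of the 34 gene lists (colour; ends at ±2) in 6 comparisons (columns); a small dot marks lists that passed camera with the preset correlation and the large dot the list that also passed with an estimated one. The male-biased list is lower by -4.24 in MCD livers.

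Green tea 1% against high fat (3 against 4 samples) gave 13 genes higher and 22 lower. The membrane protein gene Mctp1 was at least 12.9-fold higher (4.58 ± 0.37, adjusted p = 5.9e-06), followed by the non-coding RNA Dio3os (3.00 ± 0.54, adjusted p = 0.0312), Ttc6 (2.23 ± 0.37), Lgals6 (2.11 ± 0.41) and Cyp2g1 (2.05 ± 0.38). The largest falls were Cfd (-6.40 ± 0.92, adjusted p = 0.00626; from 5.09 ± 1.63 SD, n = 4, to -1.31 ± 0.49 SD, n = 3), the T cell gene Themis (-3.26 ± 0.60), Fam183b (at least 4.85-fold lower), the galectin Lgals1 (-2.89 ± 0.47) and Creld2 (-2.56 ± 0.46). The adjusted p beside each list mean is with an estimated correlation. Lipid storage genes averaged -1.16 (1 of 18 fell, 9 adjusted over the list alone; adjusted p = 0.413; set means -0.76, -1.44 and -0.86). Of these, Cd36 passed (-1.74 ± 0.32, adjusted p = 0.0337) and Cidec did not (-2.92 ± 0.75, adjusted p = 0.131). Matrix genes averaged -0.63 (0 of 24 passed, 11 adjusted over the list alone; adjusted p = 0.413), with Col1a1 at -1.76 ± 0.40 (adjusted p = 0.0884). ER stress genes averaged -0.58 (1 of 21 fell, 10 adjusted over the list alone; adjusted p = 0.533). Cell cycle genes averaged -0.75 (adjusted p = 0.413), interferon genes -0.45 and stellate cell markers -0.35 (both adjusted p = 0.533), and clock genes 0.33 (adjusted p = 0.413). Fatty acid synthesis genes averaged -0.56 and female-biased genes -0.78 (both adjusted p = 0.535), and cholesterol synthesis genes -0.32, respiratory chain genes -0.16 and hepatocyte markers -0.19 (each adjusted p = 0.828). The cholesterol list (adjusted p = 0.0698) and the female-biased list (adjusted p = 0.0992) did not pass with the array set as a block, and after quantile normalization the hepatocyte list was at -0.01 (adjusted p = 0.905) and respiratory chain genes at -0.10. Without 1 sample, calls were lost (largest adjusted p in brackets) by Cd36 without green tea 1% 3 or 4 or high fat 3 or 4 (0.132), and by Dio3os, Cyp2g1, Themis, Fam183b, Creld2, Ttc6, Lgals6 and Lgals1 each without at least 1 of green tea 1% 2, 3 or 4 or high fat 1, 3, 4 or 6 (0.0597 to 0.158). Blocking on array set gave 215 genes higher and 193 lower, the 35 among them. The total was 8 without high fat 4, 20 without green tea 1% 4 and 22 without high fat 1, and 7 lists shifted without green tea 1% 4. Without green tea 1% 2 the clock mean was 0.18. Without green tea 1% 3 the hepatocyte mean was -0.29 and respiratory chain -0.24, and the cholesterol and female-biased lists no longer passed. Without green tea 1% 4 the hepatocyte mean was -0.08, respiratory chain -0.07 and stellate cell -0.21, and the cholesterol, female-biased, hepatocyte, respiratory chain and stellate cell lists no longer passed. The cholesterol and female-biased lists no longer passed without high fat 4 or 6, nor the fatty acid synthesis and respiratory chain lists without high fat 4.

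Green tea 2% against high fat (4 against 4 samples) gave 142 genes higher and 338 lower. Cfd was lower by -7.39 ± 0.85 (adjusted p = 0.000802), the lipid droplet gene Cidea by -6.24 ± 1.08 (adjusted p = 0.00635), the heat shock gene Hspa1a by -4.00 ± 0.82, Themis by -3.99 ± 0.56 and Lgals1 by -3.32 ± 0.43. Dio3os (3.21 ± 0.50), Krtap9-3 (at least 4.92-fold higher), Amer2 (2.49 ± 0.49), Mycn (2.43 ± 0.51) and Smad9 (2.07 ± 0.42) were the largest rises. The adjusted p beside each list mean is with an estimated correlation. Lipid storage genes averaged -1.35 (9 of 18 fell, 10 adjusted over the list alone; adjusted p = 0.56; set means -1.27, -1.67 and -0.73). They included Cd36 (-1.96 ± 0.29, adjusted p = 0.00303), Cidec (-3.18 ± 0.69, adjusted p = 0.0226) and the droplet coat gene Plin2 (-1.31 ± 0.23). Matrix genes averaged -0.79 (8 of 24 fell; adjusted over the list alone 12 fell and 1 rose; adjusted p = 0.56; set means -0.44, -0.97 and -0.48), with Col1a1 at -2.40 ± 0.37 and Timp1 at -1.85 ± 0.35. ER stress genes averaged -0.70 (6 of 21 fell; adjusted over the list alone 12 fell and 1 rose; adjusted p = 0.573), with Creld2 at -2.96 ± 0.42 and the chaperone Hspa5 at -1.68 ± 0.31. Interferon genes averaged -0.64 (2 of 24 fell, 15 adjusted over the list alone; adjusted p = 0.56), with Isg15 at -0.95 ± 0.22. Inflammation genes averaged -0.76 (0 of 25 passed; adjusted over the list alone 6 fell and 1 rose; adjusted p = 0.666). Cell cycle genes averaged -0.71 (2 of 23 fell, Ccnd1 and Mcm5, and Rrm2 rose) and stellate cell markers -0.43 (1 of 16 fell) (both adjusted p = 0.573). Clock genes averaged 0.26 (adjusted p = 0.56), glucose metabolism genes 0.23 (adjusted p = 0.666) and proteasome and ribosome genes 0.05 (adjusted p = 0.805; adjusted p = 0.0591 after quantile normalization, and a mean of 0.09 with median centring). Scd1 passed narrowly (-2.28 ± 0.58, adjusted p = 0.0494), and Fasn (-0.18 ± 0.44) and Cd68 (-0.18 ± 0.22) did not. Without 1 sample, calls were lost (largest adjusted p in brackets) by Scd1 without green tea 2% 1, 2, 5 or 7 or high fat 3, 4 or 6 (0.177), Cidec without green tea 2% 5 or 7 or high fat 3 or 4 (0.0872), and by Mycn, Smad9 and Hspa1a each without at least 1 of green tea 2% 1, 5 or 7 or high fat 3, 4 or 6 (0.06 to 0.0738). Blocking on array set gave 771 genes higher and 902 lower, with all 480 among them. The total was 155 without high fat 4, 263 without high fat 3, and 283, 220 and 179 without green tea 2% 1, 5 and 7. The glucose mean was 0.38 without high fat 3 and 0.05 without high fat 6, and that list no longer passed without high fat 6 or green tea 2% 1. Without each of the 8 samples in turn the proteasome and ribosome mean ran from 0.01 to 0.10. That list no longer passed without green tea 2% 1 (0.02), green tea 2% 2 (0.01), high fat 1 (0.03) or high fat 6 (0.01).

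EGCG against high fat (3 against 4 samples) gave 100 genes higher and 121 lower. Cfd was lower by -6.56 ± 0.92 (adjusted p = 0.0053), Cidea by -5.77 ± 1.17, Cidec by -3.78 ± 0.75 (adjusted p = 0.022), Themis by -3.62 ± 0.60 and the corepressor Hr at least 6.35-fold lower. Flg2 (4.46 ± 0.85, adjusted p = 0.0175), the DNA repair gene Fancd2 (at least 6.85-fold higher), Akap5 (at least 6.92-fold higher), the glucose transporter Slc2a4 (3.05 ± 0.54) and Dio3os (2.85 ± 0.54) were the largest rises. Each list's adjusted p is with an estimated correlation. Lipid storage genes averaged -1.50 (8 of 18 fell, 12 adjusted over the list alone; adjusted p = 0.15; set means -1.62, -1.43 and -1.02), with Plin2 at -1.34 ± 0.25, Cd36 at -1.67 ± 0.32 and Pparg at -1.10 ± 0.22. Matrix genes averaged -0.71 (3 of 24 fell, 18 adjusted over the list alone; adjusted p = 0.454; set means -0.36, -1.04 and -0.38), with Col1a1 at -1.99 ± 0.40 (adjusted p = 0.0232) and Timp1 at -1.62 ± 0.38 (adjusted p = 0.0471). Fatty acid oxidation genes averaged -0.52 (3 of 28 fell; adjusted p = 0.537). Cholesterol synthesis genes averaged 0.31 (0 of 25 passed, 3 adjusted over the list alone; adjusted p = 0.634; set means 0.85, 0.49 and -0.31). ER stress genes averaged -0.68 (3 of 21 fell, 12 adjusted over the list alone) and cell cycle genes -0.72 (2 of 23 fell; adjusted over the list alone 5 fell and 1 rose) (both adjusted p = 0.454). Heat shock and immediate early genes averaged -0.77 (2 of 19 fell, 5 adjusted over the list alone; adjusted p = 0.537), interferon genes -0.39 (adjusted p = 0.634) and stellate cell markers -0.35 (adjusted p = 0.537). Clock genes averaged 0.34 and T and NK cell markers 0.32 (both adjusted p = 0.454), glucose metabolism genes 0.28 (adjusted p = 0.537) and cholangiocyte markers -0.57 (adjusted p = 0.454). The cholangiocyte list did not pass with the array set as a block (adjusted p = 0.119), nor the T and NK cell list after quantile normalization (adjusted p = 0.082), and the glucose mean was 0.18 with median centring. Without 1 sample, calls were lost (largest adjusted p in brackets) by Cidec without EGCG 2 or 6 or high fat 3 or 4 (0.127), Cd36 without EGCG 2 or 6 or high fat 4 (0.0829), Col1a1 without EGCG 2, 4 or 6 or high fat 4 (0.0909), Timp1 without EGCG 2, 4 or 6 or high fat 1, 3 or 4 (0.153), and by Flg2, Fancd2, Akap5, Slc2a4, Dio3os, Cidea, Themis and Hr each without at least 1 of EGCG 2, 4 or 6 or high fat 1 or 4 (0.0628 to 0.141). Blocking on array set gave 543 genes higher and 535 lower, with all 221 among them. The total was 11 without EGCG 2, 54 without high fat 4 and 133 without high fat 1. Without EGCG 2 the fatty acid oxidation mean was -0.26, and that list no longer passed. Without EGCG 4 the T and NK cell mean was 0.49 and cholesterol 0.16, and the cell cycle, cholangiocyte, cholesterol and stellate cell lists no longer passed. Without EGCG 6 the T and NK cell mean was 0.08 and cholesterol 0.54, and the T and NK cell and cholangiocyte lists no longer passed. Without high fat 1 the cholesterol mean was 0.19, and the cholangiocyte and cholesterol lists no longer passed. Without high fat 3 the glucose mean was 0.43. Without high fat 6 the glucose mean was 0.10, and the cholangiocyte and glucose lists no longer passed.

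Atorvastatin against high fat (3 against 4 samples) gave 41 genes higher and 51 lower. Statins lower cholesterol synthesis, and 9 of the 25 cholesterol synthesis and SREBP2 target genes rose (16 adjusted over the list alone), by 1.09 on average (adjusted p = 1.5e-27, and adjusted p = 0.0808 with an estimated correlation; 0.98, 1.12 and 1.27 in array sets 1, 2 and 3). Sqle rose 15.1-fold (3.91 ± 0.62, adjusted p = 0.0111), the methylsterol oxidase Msmo1 by 2.56 ± 0.38 (adjusted p = 0.00669), and Idi1 by 2.05 ± 0.35. Other large rises were Olfr791 (at least 6.93-fold higher) and Ripor2 (2.67 ± 0.44). The largest falls were Hspa1a (-4.82 ± 0.89, adjusted p = 0.0247), Cfd (-4.39 ± 0.92, adjusted p = 0.0441), Krt23 (-3.54 ± 0.58), the peroxisomal oxidase Hao2 (-3.03 ± 0.55) and Adig (-2.84 ± 0.55). Each list's adjusted p is with an estimated correlation. Matrix genes averaged -0.82 (2 of 24 fell, 17 adjusted over the list alone; adjusted p = 0.215; set means -0.65, -1.15 and -0.30), with Col1a1 at -2.00 ± 0.40 (adjusted p = 0.0356). Lipid storage genes averaged -1.06 (1 of 18 fell, 8 adjusted over the list alone; adjusted p = 0.285; set means -0.85, -1.41 and -0.49), with Mest at -1.34 ± 0.27 and Cd36 at -1.36 ± 0.32 (adjusted p = 0.0712). ER stress genes averaged -0.71 (2 of 21 fell, 13 adjusted over the list alone) and cell cycle genes -0.66 (1 of 23 fell) (both adjusted p = 0.331). Fatty acid oxidation genes averaged -0.49, stellate cell markers -0.33, female-biased genes -0.78 (1 of 17 fell) and clock genes 0.16 (each adjusted p = 0.467), and cholangiocyte markers -0.75 (1 of 11 fell, Krt23; adjusted p = 0.321). With the array set as a block the clock and cholangiocyte lists (both adjusted p = 0.0544) and the female-biased list (adjusted p = 0.0808) did not pass, nor did the clock list after quantile normalization (adjusted p = 0.0656). Without 1 sample, calls were lost (largest adjusted p in brackets) by Sqle without atorvastatin 8 or 10 (0.0593), Cfd without atorvastatin 7, 8 or 10 or high fat 3, 4 or 6 (0.203), Col1a1 without atorvastatin 7, 8 or 10 or high fat 1, 3 or 4 (0.183), Msmo1 without atorvastatin 8 (0.0517), and by Hspa1a, Hao2, Adig, Ripor2 and Krt23 each without at least 1 of atorvastatin 7, 8 or 10 or high fat 1, 3 or 4 (0.0771 to 0.115). Blocking on array set gave 277 genes higher and 233 lower, with all 92 among them. The total was 11, 17, 32, 34 and 61 without atorvastatin 8, high fat 4, atorvastatin 10, atorvastatin 7 and high fat 1, respectively. The clock list no longer passed without atorvastatin 10, high fat 1 or high fat 3, the female-biased list without atorvastatin 8, high fat 4 or high fat 6, the stellate cell list without atorvastatin 8 and the cholangiocyte list without high fat 1. Without high fat 6 the clock mean was 0.10.

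Comparing the treatments with each other asks whether dose, or the pure catechin instead of the extract, made a difference. Mctp1 stood out. Its signal was above background in the 3 green tea 1% livers and at background at the higher dose, at least 15.2-fold lower (-4.86 ± 0.37, adjusted p = 2.17e-06), and in EGCG livers, at least 14.5-fold lower (-4.81 ± 0.40, adjusted p = 7.82e-06). Green tea 2% against 1% gave 1 gene higher, Krtap9-3 (at least 5.59-fold higher), and 3 lower (6 genes with the array set as a block). EGCG against green tea 1% gave 1 higher, the ribosomal RNA probe Rs5-8s1 (1.96 ± 0.30, adjusted p = 0.018), and 3 lower (11 with the block). EGCG against green tea 2% gave 0 genes with limma, 960 (below chance) at an unadjusted p under 0.05 and 1 with the block. The smallest adjusted p values there were 0.0566 for Igsf23 (-1.83 ± 0.28) and Olfr1255. The doses differ, at 20 mg/kg for EGCG and 100 or 200 mg/kg for the extract. The median 95% interval of a gene reached 0.65 to either side (0.69 for EGCG against green tea 1%), so changes of that size were not detectable for most genes.

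By list, cholesterol synthesis genes lay higher in EGCG than in extract livers, by 0.57 against green tea 2% (24 of 25 above 0; adjusted p = 1.84e-11, and adjusted p = 0.752 with an estimated correlation) and by 0.63 against green tea 1% (adjusted p = 4.64e-15, and adjusted p = 0.236 with an estimated correlation). Fatty acid synthesis genes lay higher by 0.49 and 0.57 (adjusted p = 0.752 and 0.236), with Fasn at 1.73 ± 0.47 and 2.15 ± 0.50, and fatty acid oxidation genes lower by -0.31 and -0.38 (adjusted p = 0.989 and 0.732), each p with an estimated correlation. The other lists lost their calls with an estimated correlation too. Against green tea 2% they were interferon genes at 0.25, male-biased genes at -0.21 (both adjusted p = 0.992) and xenobiotic metabolism genes at -0.18 (adjusted p = 0.989). Against green tea 1%, with an estimated correlation, they were heat shock and immediate early genes at -0.78 (adjusted p = 0.236), male-biased genes at -0.37 (adjusted p = 0.732), lipid storage genes at -0.34 and female-biased genes at 0.49 (both adjusted p = 0.758), hepatocyte markers at 0.19 (adjusted p = 0.898), and glucose metabolism genes at 0.14 and pancreas markers at 0.49 (both adjusted p = 0.917). The pancreas set means were 0.04, 1.62 and -0.20. After quantile normalization the glucose and pancreas lists (both adjusted p = 0.0513) and the female-biased list (adjusted p = 0.079) no longer passed. The female-biased list also lost its call with the array set as a block (adjusted p = 0.0761), and the glucose list with median centring (0.06, adjusted p = 0.0773). The hepatocyte mean was 0.10 after quantile normalization and 0.11 with median centring. Against green tea 2%, median centring gave interferon 0.11, male-biased -0.35 and xenobiotic -0.32. No member of these lists passed over all genes. EGCG against green tea 2% gave 4, 5 and 26 without EGCG 2, 4 and 6. EGCG against green tea 1% gave 10, 14 and 12 without green tea 1% 2, 3 and 4 and 10 and 22 without EGCG 2 and 6.

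Leaving out 1 sample changed many of these lists. For EGCG against green tea 2%: without EGCG 2 the fatty acid oxidation mean was -0.06 and xenobiotic -0.04, and these and the male-biased list no longer passed. Without EGCG 4 the fatty acid oxidation mean was -0.53 and xenobiotic -0.35, and the male-biased list no longer passed, nor the interferon list without EGCG 6 or green tea 2% 1 (0.14). Without green tea 2% 2 the interferon mean was 0.39, male-biased -0.13 and xenobiotic -0.10, and the last 2 no longer passed. Without green tea 2% 7 the male-biased mean was -0.33. For EGCG against green tea 1%: without EGCG 2 the fatty acid oxidation mean was -0.12 and lipid storage -0.16, and both no longer passed. Without EGCG 4 the fatty acid oxidation mean was -0.60, female-biased 0.24, glucose 0.07, hepatocyte 0.10, lipid storage -0.58 and pancreas -0.08, and the female-biased, glucose and pancreas lists no longer passed. Without EGCG 6 the hepatocyte mean was 0.29 and pancreas 0.82, and the female-biased and glucose lists no longer passed. With green tea 1% 2 left out the female-biased mean was 0.88 and male-biased -0.65, and the lipid storage list no longer passed. With green tea 1% 3 left out the female-biased mean was 0.24, glucose 0.28, hepatocyte 0.29, heat shock -0.52 and male-biased -0.17, and the female-biased, male-biased and pancreas lists no longer passed. With green tea 1% 4 left out the glucose mean was -0.02 and hepatocyte 0.08, and the female-biased, glucose and male-biased lists no longer passed.

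The 2 extract doses differed in 3 lists. Green tea 2% had heat shock and immediate early genes at -0.70, interferon genes at -0.19 and NRF2 and glutathione genes at 0.17 against green tea 1% (each adjusted p = 0.956 with an estimated correlation; the NRF2 list had adjusted p = 0.365 after quantile normalization). With median centring neither the interferon list (-0.13, adjusted p = 0.104) nor the NRF2 list (adjusted p = 0.0636) passed. Of the immediate early genes, Fos was at -2.17 ± 0.84. No member of these lists passed over all genes. Green tea 2% against 1% gave 13, 24 and 12 genes without green tea 1% 2, 3 and 4 and 7 without green tea 2% 1. With green tea 1% 2 left out the NRF2 mean was 0.27. With green tea 1% 3 left out the heat shock mean was -0.44 and interferon 0.00, and the interferon list no longer passed. With green tea 1% 4 left out the NRF2 mean was 0.02 and interferon -0.30, and the NRF2 list no longer passed. With green tea 2% 1 left out the interferon mean was -0.08, and the interferon list no longer passed. With green tea 2% 2 left out the NRF2 mean was 0.10 and interferon -0.33, and the NRF2 list no longer passed. With green tea 2% 7 left out the interferon list no longer passed.

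The treatments against low fat ask how far the treated livers stood from livers on the standard diet. Clock genes averaged 0.78, 0.71, 0.79 and 0.62 higher with green tea 1%, green tea 2%, EGCG and atorvastatin (0.45 in high fat). This list passed with an estimated correlation in all 4, which share the low fat samples (adjusted p = 0.0235, 0.032, 0.0271 and 0.0232). The deubiquitinase gene Usp2 rose by 2.44 ± 0.37, 2.44 ± 0.35, 2.47 ± 0.37 and 2.19 ± 0.37, Ciart by 2.62 to 3.09 and Per3 by 2.38 to 3.06. Of the 21 members, 4, 5, 3 and 3 rose over all genes and 11, 12, 14 and 11 adjusted over the list alone, where 3, 3, 3 and 2 fell. Cholesterol synthesis genes averaged 1.21 higher with atorvastatin (6 of 25 rose, 18 adjusted over the list alone with 1 that fell; adjusted p = 0.0232 with an estimated correlation), with Sqle 18.5-fold higher. Lipid storage genes averaged -0.83, -1.03, -1.17 and -0.74 (adjusted p = 0.575, 0.538, 0.151 and 0.499 with an estimated correlation), with Cd36 at -2.00 ± 0.34, -2.21 ± 0.32, -1.93 ± 0.34 and -1.62 ± 0.34. Cd36 passed in all but atorvastatin (adjusted p = 0.0788).

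Other lists passed with the preset correlation and lost their calls with an estimated one, whose adjusted p is in brackets. In the 4 treatments the means were, for matrix genes, -0.35, -0.50, -0.42 and -0.53 (adjusted p = 0.893, 0.698, 0.578 and 0.499), for respiratory chain genes -0.30, -0.26, -0.24 and -0.25 (adjusted p = 0.589, 0.698, 0.578 and 0.661) and for stellate cell markers -0.29, -0.38, -0.29 and -0.28 (adjusted p = 0.725, 0.698, 0.595 and 0.667). With an estimated correlation interferon genes with green tea 1%, green tea 2% and EGCG (-0.49, -0.68 and -0.43; adjusted p = 0.589, 0.538 and 0.578), hepatocyte markers with green tea 1%, green tea 2% and atorvastatin (-0.29, -0.22 and -0.22; adjusted p = 0.725, 0.875 and 0.828) and heat shock and immediate early genes with green tea 2%, EGCG and atorvastatin (-0.87, -0.95 and -0.58; adjusted p = 0.61, 0.475 and 0.667) lost their calls too. So did glucose metabolism genes (0.14 and 0.19; adjusted p = 0.698 and 0.578) and T and NK cell markers (0.18 and 0.39; adjusted p = 0.61 and 0.475) with green tea 2% and EGCG, and fatty acid oxidation genes with EGCG and atorvastatin (-0.57 and -0.54; adjusted p = 0.578 and 0.538). The lists of 1 treatment were skeletal muscle with green tea 1% (-0.64; adjusted p = 0.575), xenobiotic (0.10; adjusted p = 0.698) and red blood cell (-0.75; adjusted p = 0.781) with green tea 2%, cholesterol with EGCG (0.44; adjusted p = 0.578), and neutrophil (0.54; adjusted p = 0.667) and cholangiocyte (-0.63; adjusted p = 0.499) with atorvastatin, again with an estimated correlation.

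With the array set as a block the calls lost were the matrix, muscle (both adjusted p = 0.0557) and stellate cell lists (adjusted p = 0.0623) with green tea 1%, red blood cell with green tea 2% (adjusted p = 0.101), stellate cell with EGCG (adjusted p = 0.0887), and heat shock (adjusted p = 0.0532) and cholangiocyte with atorvastatin (adjusted p = 0.261). After quantile normalization they were the 3 hepatocyte lists (-0.04, -0.01 and -0.05; adjusted p = 0.629, 0.793 and 0.768) and T and NK cell with green tea 2% (adjusted p = 0.0625). There the respiratory chain means were -0.16, -0.17, -0.14 and -0.13, and with green tea 2% glucose was 0.21 and xenobiotic 0.19. With median centring the hepatocyte list was lost with green tea 2% (adjusted p = 0.0655), and glucose was 0.09 with EGCG. Leaving out 1 sample, the lists lost with green tea 1% were matrix without green tea 1% 4 (-0.22) or low fat 1, stellate cell without green tea 1% 3, 4 (-0.16) or low fat 6, and muscle without green tea 1% 3 or 4 or low fat 1 or 4, and hepatocyte was -0.19 and -0.18 without green tea 1% 4 and low fat 4. With green tea 2% they were red blood cell without green tea 2% 2 or 5 or low fat 1 or 4, heat shock and stellate cell without low fat 6, hepatocyte without low fat 4 (-0.11), T and NK cell without green tea 2% 5 (0.10) or low fat 4, and xenobiotic without green tea 2% 2 (0.01) or low fat 1 (0.02). T and NK cell was 0.11 without green tea 2% 2 and 0.10 without low fat 1, xenobiotic 0.15 without green tea 2% 1 or low fat 4, and glucose 0.07, 0.08 and 0.22 without green tea 2% 1, 2 and low fat 4. With EGCG the lists lost were stellate cell without EGCG 4 or low fat 6 and T and NK cell without EGCG 6 (0.16) or low fat 4. Cholesterol was 0.67 without EGCG 6 and 0.29 without low fat 1, fatty acid oxidation -0.32 without EGCG 2 and -0.31 without low fat 1, respiratory chain -0.13 and -0.39 without EGCG 2 and 4, and glucose 0.12 without EGCG 4. With atorvastatin the lists lost were neutrophil without atorvastatin 8 (-0.02) or low fat 4, hepatocyte without low fat 4 (-0.10), heat shock without atorvastatin 7, 10 (-0.36) or low fat 6 (-0.38), stellate cell without atorvastatin 8 or low fat 6, and cholangiocyte without atorvastatin 7 or 8 or low fat 1, 4 or 6. Neutrophil was 0.90 without atorvastatin 10, and lipid storage -0.47 and fatty acid oxidation -0.28 without low fat 1.

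**Figure D4:**
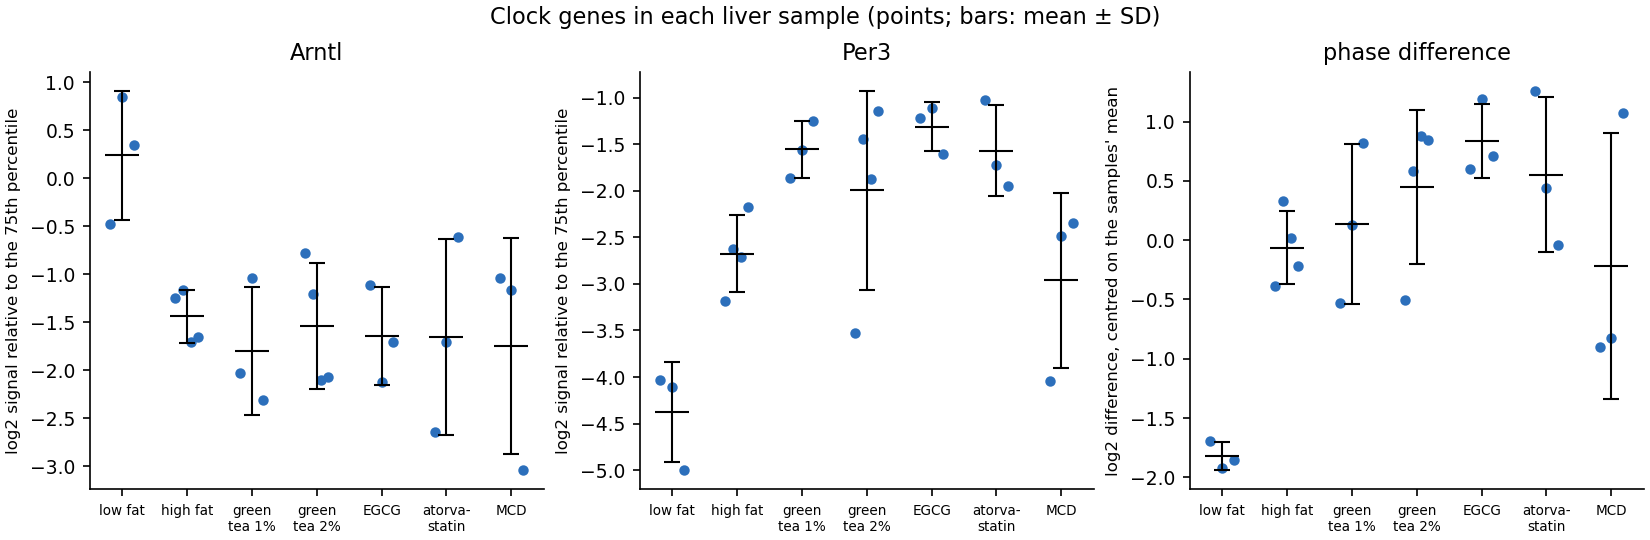
Arntl and Per3 (log2 signal relative to the array's 75th percentile) and the mean of 12 genes of the Dbp and Per phase minus that of 4 genes of the Arntl phase (log2, centred) in each sample (points), with group means and SD (bars). The 3 low fat livers have the lowest phase differences of all samples, and the treated livers average 2.31 above them.

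By gene, green tea 1% against low fat gave 24 higher and 24 lower (506 in all with the array set as a block), green tea 2% 91 and 151 (1290), EGCG 58 and 39 (801) and atorvastatin 20 and 12 (235). Green tea 1% livers had more Rbmy (at least 18.5-fold higher) and less Scd3 (-4.02 ± 0.65), and green tea 2% livers more of the asparagine synthetase Asns (3.96 ± 0.83) and less Scd3 (-3.77 ± 0.61). EGCG livers had more Flg2 (at least 21.3-fold higher) and Cyp7a1 (3.70 ± 0.61, adjusted p = 0.0107) and less of the stress cytokine Gdf15 (-3.44 ± 0.54), and atorvastatin livers more Sqle (4.21 ± 0.66) and Cyp7a1 (3.64 ± 0.61, adjusted p = 0.0257) and less Krt23 (-3.36 ± 0.62). Leaving out 1 sample moved the count for green tea 1% to 17, 20, 25 and 24 without low fat 1, 4, 6 and green tea 1% 4, and for green tea 2% to 63, 53, 123, 93 and 72 without low fat 1, 4, 6 and green tea 2% 5 and 7. It moved to 46, 45, 37 and 27 for EGCG without low fat 1, 4, 6 and EGCG 2, and to 10, 5, 1, 21, 8 and 11 for atorvastatin without low fat 1, 4, 6 and atorvastatin 7, 8 and 10.

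Whether a treatment returned the liver towards the low fat state was tested with the 4 high fat samples split 2 and 2, so that the diet change and the treatment change shared no sample. Across 24136 genes, which are not independent replicates, the correlation of the diet change with the treatment change was 0.0217 for green tea 1%, -0.0240 for green tea 2%, -0.0137 for EGCG and -0.0437 for atorvastatin. A return gives a negative value, and simulations that ignored the array sets gave 95% ranges from -0.297 to 0.407, -0.250 to 0.396, -0.328 to 0.388 and -0.244 to 0.438. With all high fat samples on both sides the covariances were -0.0586, -0.0695, -0.0675 and -0.0738, beside -0.0735, -0.0801, -0.0773 and -0.0739 in the simulations. Sptlc3 and Slc10a2 passed in high fat against low fat and were lower in all 4 treatments than in high fat. The same high fat samples selected them, which favours a fall. Sptlc3 was near background in all treated livers and at least 2.80-fold to 2.95-fold lower, and Slc10a2 was lower by -1.37 to -2.11.

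The overlap of the treatments asks whether they changed the same genes. Green tea 2% and EGCG shared 168 genes that moved in the same direction, 64 of them higher. These comparisons share the 4 high fat samples, which adds shared genes by itself, and no count without a treatment change was computed. With the high fat samples split between the treatments, the correlation across genes was 0.314, 0.275, 0.180, 0.323, 0.238 and 0.226 for green tea 1% with 2%, with EGCG and with atorvastatin, green tea 2% with EGCG and with atorvastatin, and EGCG with atorvastatin. Over the 6 pairs it averaged 0.259, against -0.0276 (SD 0.136) in the 100 simulations. Pair by pair it lay above the simulated 95% range for EGCG with green tea 1% (upper end 0.263) and 2% (upper end 0.288). The other 4 pairs lay within it. Without the split, the covariance exceeded the simulated one by 0.0842, 0.0740, 0.0470, 0.0882, 0.0542 and 0.0549 in the same order.

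The lists that passed in no comparison were one-carbon and methionine metabolism (25 genes, means from -0.19 to 0.20), B and plasma cell (11 genes, -0.46 to 0.34) and sinusoidal endothelium (15 genes, -0.19 to 0.09). The others were adipose tissue (10 genes, -1.36 to 0.44, smallest adjusted p = 0.0884), intestine and kidney (12 genes, -0.44 to 0.14) and olfactory receptor genes, which liver is not expected to express (1104 genes, -0.33 to 0.07).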

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

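Gene lists, comparisons and alternatives were chosen before the data were examined. The exceptions are the treatment of low fat arrays 1 and 3 with its alternatives, the array set in the tests of lists, return and overlap, and the means of lists without 1 sample. The tests of single samples and of probes without a symbol follow rules set beforehand.

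In 5 of 120 groups of values, 1 sample lay far from the others relative to the group's range; chance gives about 5 percent of groups. The acute phase gene Saa1 was lower in high fat 3 (6.58, others 7.16 to 7.20; gap over range 0.932), and Ttc6 was lower in the same sample (-5.14, others -3.59 to -3.37; 0.874). Amer2 was higher in green tea 2% 1 (-0.71, others -2.83 to -2.52; 0.855), and Fasn was higher in that sample too (-0.01, others -0.99 to -0.91; 0.913). Saa1 was lower in green tea 2% 5 (4.18, others 5.18 to 5.35; 0.853).

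Among the 22480 probes without a gene symbol, which no comparison of genes uses, 1016 passed for MCD against low fat (325 higher and 691 lower). Against high fat, 1 passed for green tea 1% (higher), 54 for green tea 2% (18 higher and 36 lower), 26 for EGCG (19 and 7) and 8 for atorvastatin (5 and 3).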

How the results depend on the processing

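The alternatives below were fixed before the data were examined, except the treatment of low fat arrays 1 and 3, the array set as a block for lists, return and overlap, and the list means without 1 sample, all chosen later. Counts are genes with limma's adjusted p under 0.05, and a count is given where it moved by more than 1.5 times, with the 4 treatments in the order green tea 1%, green tea 2%, EGCG and atorvastatin. Over all alternatives, 136 gene counts stayed within 1.5 times and 166 moved, and for lists 95 stayed and 11 moved. The 93 values of the return and 22 of the overlap moved by less than 1 SD of the simulations. For the return that SD (0.169 to 0.184) is wider than the 4 return values given above, and their sign changed between settings, with ranges from -0.0690 to 0.0931, -0.152 to 0.0670, -0.154 to 0.0532 and -0.182 to 0.0392. The overlap, with an SD of 0.136, ran from 0.160 to 0.333. Of 3704 recomputed values of named genes, 3384 kept their state (passing or not), 264 lost a call, 56 gained one and 0 changed sign while passing. The cause of these moves was not tested unless stated.

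Scaling and filters. With quantile normalization the counts were 94 (46 higher and 48 lower), 946, 486 and 249 for the 4 treatments against high fat, 4 for EGCG against green tea 2%, and 163, 531, 237 and 70 for the 4 treatments against low fat. With median centring they were 0 for high fat, 2935 for MCD and 25, 78 (46 higher and 32 lower), 35 and 20 (16 higher and 4 lower) for the 4 treatments against low fat, and 14 (7 higher and 7 lower), 163, 92 (27 higher and 65 lower) and 26 for the 4 treatments against high fat. With only the brighter probes (above the median level) they were 1 for high fat and 117, 505, 244 and 72 (36 higher and 36 lower) for the 4 treatments against low fat, 95, 901, 428 and 226 for the 4 treatments against high fat, 0 for green tea 2% and 1 for EGCG (1 higher and 0 lower) against green tea 1%, and 2 for EGCG against green tea 2%, and with no filter on dim probes, which is also the setting used, nothing changes. The mean over a gene's probes gave 0 for high fat against low fat, and 4 for EGCG against green tea 2%, and every probe on its own gave 0 for high fat and 17 for atorvastatin against low fat, 11 for green tea 1% and 60 for atorvastatin against high fat, 3 for EGCG against green tea 2%, and 9 for EGCG against green tea 1%. Over 144 passing lists, 0 means changed sign under quantile normalization or median centring, and 21 of 288 values no longer passed.

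Fit and source. A fit of the 2 groups alone gave 0 for high fat, 1500 for MCD and 7, 46, 4 and 0 for the 4 treatments against low fat, 2488 for MCD and 6, 68, 4 and 0 for the 4 treatments against high fat, 0 for green tea 2% and 1 for EGCG against green tea 1%, and 1 for EGCG against green tea 2%; it has fewer degrees of freedom by construction. Array weights gave 5 for high fat and 562, 952, 238 and 778 for the 4 treatments against low fat, 797, 2565, 512 and 1603 for the 4 treatments against high fat, 163 for green tea 2% against green tea 1%, and 6 for EGCG against green tea 2%. A trend and robust prior gave 76 for green tea 1%, 335 for EGCG and 175 for atorvastatin against high fat, 3 for EGCG against green tea 2%, and 114, 366, 195 and 75 for the 4 treatments against low fat. The deposited log2 values, centred within each array set by construction, gave 6 for high fat, 7544 for MCD and 537, 1140, 875 and 199 for the 4 treatments against low fat, 8053 for MCD and 387, 1516, 1147 and 526 for the 4 treatments against high fat, 7 for green tea 2% and 15 for EGCG against green tea 1%, and 8 for EGCG against green tea 2%. Adding a 2-fold threshold gave 2515 for MCD against low fat, and 2605 for MCD and 270 for green tea 2% against high fat.

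Array set and replicate numbers. With the array set as a block the counts were 7177 for MCD and 506, 1290, 801 and 235 for the 4 treatments against low fat, 7663 for MCD and 408, 1673, 1078 and 510 for the 4 treatments against high fat, 1 for EGCG against green tea 2%, and 11 for EGCG against green tea 1%. Residuals of samples in the same set correlated at a median of 0.413 over 75 pairs, and those in different sets at -0.134. Replicate numbers do not pair the samples: 24 pairs with the same number had a median correlation of 0.0930 (from -0.614 to 0.595), 11 of them above 0.1, other pairs had -0.0428, and 2 of 21 samples correlated best with their own number, over 12068 genes. A block of replicate numbers gave 0 for high fat, 1 for green tea 2%, 5 for EGCG and 1 for atorvastatin against low fat, 12, 7, 0 and 2 for the 4 treatments against high fat, and 1 for EGCG against green tea 2%.

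With low fat arrays 1 and 3 as separate samples the counts were 3 for EGCG against green tea 2%, and 166, 528, 331 and 83 for the 4 treatments against low fat. With an estimated correlation between genes, the numbers of lists were 0 for high fat against low fat, 1 for MCD against low fat, and 0 for each treatment against high fat.

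Leaving out 1 sample at a time gave counts of 0 to 5 for high fat, 3079 to 4515 for MCD and 17 to 57, 53 to 263, 27 to 108 and 1 to 33 for the 4 treatments against low fat, 3384 to 4985 for MCD and 8 to 40, 155 to 438, 11 to 195 and 11 to 66 for the 4 treatments against high fat, 3 to 24 for green tea 2% and 4 to 22 for EGCG against green tea 1%, and 0 to 26 for EGCG against green tea 2%. The lists numbered 4 to 11 for high fat and 14 to 18 for MCD against low fat, and 7 to 16, 8 to 14, 10 to 15 and 9 to 12 for the 4 treatments against high fat. Over the 14 comparisons, 4 passing list means changed sign without 1 sample.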

Other observations

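The MCD diet lacks methionine and choline, and genes of one-carbon and methionine metabolism moved in both directions. Of 25 one-carbon and methionine genes, 5 were higher and 10 lower than in low fat livers, with a list mean of 0.12 (adjusted p = 0.252). The serine synthesis genes Psat1 and Phgdh were at 6.40 (adjusted p = 9.63e-08) and 2.32 (adjusted p = 0.000136) and the mitochondrial folate gene Mthfd2 at 2.83 (adjusted p = 0.00621). The methyl cycle genes Ahcy, Cbs, Bhmt and Gnmt were at -1.02 (adjusted p = 0.00041), -0.96 (adjusted p = 0.00871), -0.94 (adjusted p = 0.0322) and -0.80 (adjusted p = 0.0175).

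The tests of array set, adipose tissue and each untreated group in the next paragraph, and of sampling time in the one after, were chosen only after the result was seen.

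In 63 genes of lipid storage, matrix and ER stress, the 13 treated livers lay lower than the mean of the low fat and high fat groups, by -0.683 (SE 0.0991). Against high fat the difference was -0.865 (SE 0.120). Against low fat, lipid storage and matrix genes differed by -0.661 (SE 0.169), while ER stress genes were at -0.183 (SE 0.222), with 0.575, -0.154 and -0.912 in array sets 1, 2 and 3. With array brightness as a covariate the pooled difference was -0.446 (SE 0.102), which argues against brightness as the whole cause. By list, lipid storage genes then differed by -1.07 (SE 0.253) and matrix genes by -0.522 (SE 0.130) from high fat, and lipid storage genes by -0.704 (SE 0.293) from low fat. Brightness stays open for ER stress genes against high fat (-0.440, SE 0.224) and matrix genes against low fat (-0.189, SE 0.151). Within array sets the pooled difference was -0.539 at its nearest to 0, and -0.650 (SE 0.0594) with the set as a block. By list, the values nearest to 0 were -0.763, -0.411 and -0.522 for lipid storage, matrix and ER stress genes against high fat. They were -0.499 and -0.405 for lipid storage and matrix genes against low fat. These argue against the array set. Adipose tissue in the untreated samples stays open. The 9 adipose markers outside these lists averaged -0.506 (SE 0.125), with Cfd at -3.98 (SE 0.567), Car3 -0.939 (SE 0.256), Retn -0.617 (SE 0.184) and Fabp4 -0.367 (SE 0.161), but Adrb3 1.18 (SE 0.295). Without Cfd the mean was -0.0722 (SE 0.102). Lep (-0.136), Plin1 (0.360) and Adipoq (0.0395, SE 0.388) lay near background in 19, 17 and 6 of 20 samples. An effect shared by the treatments, or by how the treated mice were handled, may explain the pattern, and the design has no vehicle group to part them.

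Clock genes were ordered low fat, high fat, treated. The mean of 12 genes of the Dbp and Per phase minus that of 4 genes of the Arntl phase was higher by 2.31 in treated than in low fat livers (exact permutation p = 0.00179, the smallest that 560 splits can give). These genes belong to the list whose shift prompted the test, so the small p supports no cause. The labels give no time of sampling, and a different time stays open and was not tested on other genes. The same difference was higher by 1.76 in high fat than in low fat (exact permutation p = 0.0286, the smallest that 35 splits can give), by 0.553 in treated than in high fat (exact permutation p = 0.0916, 2380 splits) and by 1.60 in MCD than in low fat (exact permutation p = 0.1, the smallest that 20 splits can give). The smallest treated minus low fat value within an array set was 1.69, which argues against the array set. A direct effect of diet on the clock stays open.

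Few genes differed between high fat and low fat. The 12 exchanges of 1 high fat and 1 low fat label gave 0 genes with limma (real labels 2). A small effect could give this with or without a swap. The simulated data gave calls at this sample size, for 50% of genes changed 2-fold.

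Other splits of the same samples test whether chance gives as many genes. For high fat against low fat, 4 of 35 splits gave at least the real 2 (highest other 3), so chance is not excluded. Among splits that ignore the array sets, the real split gave most genes for MCD against high fat (1 of 35; real 4946, highest other 1715, with high fat 6 on the MCD side). Against high fat it also did (1 of 35 each) for green tea 1% (35, highest other 4), green tea 2% (480, other 0), EGCG (221, other 8) and atorvastatin (92, other 6). The same holds for green tea 2% against low fat (1 of 35; 242, highest other 15). Other splits gave at least as many for green tea 2% against 1% (2 of 35; 4, highest other 6) and EGCG against green tea 2% (35 of 35; 0, highest other 4). The 10 splits are too few for MCD against low fat (real 4405, highest other 1), EGCG against green tea 1% (4, other 2), and green tea 1% (48, other 0), EGCG (97, other 0) and atorvastatin (32, other 1) against low fat. These splits exchange samples across the array sets, whose samples resemble each other, and are uncorrected over comparisons, so they cannot exclude chance. The splits that keep each side's numbers per set are 18 for green tea 2% against high fat, 12 for the other comparisons with 35 splits and 4 for those with 10, too few for 1 in 20. Among these the highest other was 1419 for MCD, 1 for green tea 1%, 0 for green tea 2%, 3 for EGCG and 3 for atorvastatin against high fat.

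For the number of lists chance is not excluded among splits that ignore the array sets: 23 of 35 splits gave at least the real 7 for high fat against low fat (highest other 16), 7 of 35 the real 12 for green tea 1% (15), 5 of 35 the real 10 for green tea 2% (16), 7 of 35 the real 13 for EGCG (16) and 9 of 35 the real 10 for atorvastatin (14) against high fat. For MCD against low fat the 10 splits are too few (real 15, highest other 20, and 6 of 10 gave at least 15).

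High fat 4, not flagged above, was its group's lowest for Hsd3b5 (2.71, others 5.77 to 7.12). It was highest for Cidea (6.83, others 0.42 to 3.40) and Cfd (7.22, others 3.50 to 5.42). One Xist probe was high on low fat array 3 (8.75; 1.60 on low fat array 1) and in high fat 3 (6.31), while the gene's other probe was at 2.08, 1.83 and 2.30. For genes that passed, other probes had the same sign in 1612 of 1990 cases for MCD against low fat, and against high fat in 10 of 12 for green tea 1%, 161 of 198 for green tea 2%, 65 of 78 for EGCG and 31 of 34 for atorvastatin. Signal includes background, so folds of dim genes are compressed, and between 33.7% and 48.6% of probes per array lay near the floor.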
